A study of Mus musculus with 4 samples.

How the data were processed

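RNA sequencing of 4 mouse samples was used: nESC of the lines R1 and E14 and EpiLSC of the same lines, 2 samples per state. Per the labels, total RNA was depleted of ribosomal RNA and made into strand-specific libraries. The submitters' processing notes name TopHat2, HTSeq and DESeq2 1.8.2 and the genome build mm9. The gene annotation, the strand setting of the counting and the versions of TopHat2 and HTSeq are not given in the sources used here.

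The 1 file was the authors' comparison table, with no column per sample. Its first measure, the mean of normalized counts over the libraries, is a signal that the authors made by dividing counts by size factors. The deposited log2 fold changes and their standard errors were made by the authors with the model of DESeq2, per the file headers and the submitters' processing notes. The deposited Wald score equalled the fold change divided by its standard error, with a largest gap of 5.9e-14. The deposited p-value was the two-sided normal p-value of that score (largest gap 2.9e-15), and the authors' adjusted p was the Benjamini-Hochberg value over the 16361 genes that have one (largest gap 2.3e-15). The other 3935 genes, with a mean of up to 3.74, have no adjusted p and were not counted as tested.

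The low means were whole-read sums of 4 steps, 1 per library: of 2368 means below 1.5, 100.0% lay on such sums within 1e-06, against 0.0% after each value was moved at random. The steps gave size factors from 0.735 to 1.28, and 2 of the 4 libraries had each sign of fold change in genes seen in 1 library alone. No library was assigned to a line and no counts per library were rebuilt. Total reads per sample are unknown. Precision is that of the standard errors, which had a median of 0.68 among 4949 genes with a mean of 1000 or more and 1.3 among 5648 tested genes with a mean below 100. The most abundant gene held 1.45% of the summed means and the 13 mitochondrial protein genes 3.07%.

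The design fixed before the data were examined foresaw such a table: no new test of single genes, and the deposited values. Genes with an adjusted p under 0.05 were counted as risen or fallen, also with a fold of 2 or more. The direction was set from Fgf5, Otx2, Dnmt3b, Zfp42, Klf4 and Esrrb. Levels per state were computed from the mean m and the log2 fold change L as 2m/(1 + 2^L) for nESC and the rest of 2m for EpiLSC, which assumes equal weights for the 4 libraries. A level under 3 was taken as resting on few reads. The 95% intervals are the fold change plus or minus the normal quantile times the standard error.

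Gene names, biotypes, neighbours and transcript GC came from GENCODE M21, which is built on GRCm38, so no coordinates are given. Of the 20296 gene IDs 20167 had a name, matched without the version, and 129 had none.

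The 28 gene lists, with 608 members, of which 577 were in the table, were fixed before the data were examined. They cover naive, formative and core pluripotency, glycolysis and other metabolism, signalling targets, other cell types, germline and imprinted genes, adhesion, the cell cycle, long noncoding RNAs and structural RNAs. The planned camera test needs values per sample, so 27 lists with at least 5 tested members were tested with limma 3.58.1's cameraPR (R 4.3.3), which compares the deposited Wald scores of a list with those of other genes, at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The median of each list was also placed among 10000 random lists matched on mean level in 20 bins.

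The named genes were chosen by a rule fixed before the data were examined: Lncenc1, the 8 largest rises and 8 largest falls among called genes with a mean in the upper 50% of tested genes; 19 genes of pluripotency and glycolysis; 2 members of each list in each direction with the smallest p; and 5 long noncoding RNAs each way, of which only 2 that rose met the rule. Movement in the same direction in both lines, and genes that differ between the lines, were part of the rule and could not be evaluated. Ldhb, Hk1, Tead2, Cdh2, Tet3, Zeb2, Twist1, Xist, Tsix, Hprt, Gm26917 and, in the closing part, genes outside this rule were named after their values were seen.

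The calls were tested on simulated data: 50 tables of 16361 genes with the deposited standard errors and 200 changed genes each. Of the calls 5.1% were false, and among genes with a mean of 1000 or more a 4-fold change was called in 23.0% and a 16-fold change in 95.1%. Errors were drawn at the deposited standard errors, so the share of false calls checks only the adjustment. With fewer changed genes than the 2274 called in the real table, the threshold was stricter, so the real shares called are likely higher. Of list tests on simulated unchanged genes 3.07% had p under 0.05, and a glycolysis list with each Wald score shifted by 1 unit was called in 97 of 100 tables. The simulated scores had an SD of 1, whereas 13.9% of tested genes were called in the real table. Real scores thus spread more widely, so a shift of 1 unit would be called less often there.

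Alternatives used no filter beyond a nonzero total, a fold of 2 or more and, chosen after the data were seen, a test against a 2-fold change, a mean of 100 or more, fold changes recentred at their median, a preset correlation of 0.05 and the named long noncoding RNAs without the Platr RNAs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.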

Results

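RNA was sequenced from naive mouse embryonic stem cells (nESC) and from epiblast-like stem cells (EpiLSC), which correspond to the epiblast shortly after implantation. The nESC were kept in 2i/LIF medium, where 2 kinase inhibitors and the cytokine LIF hold cells in the naive state. EpiLSC were collected on day 3 of culture with the growth factors bFGF at 12 ng/ml and activin A at 20 ng/ml. Each state had 2 samples, 1 from the embryonic stem cell line R1 and 1 from E14TG2a (E14). The values came from 1 comparison table of 20296 genes, so levels of single samples, differences between R1 and E14, and their SDs were not analysed here. The 4 samples differ in line or medium and so were separate cultures, but each line was sampled only 1 time per state. The spread between the 2 samples of a state therefore includes the difference between R1 and E14. The p-values come from the authors' DESeq2 model of these 4 samples and do not measure variation between repeat cultures of a line.

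The direction of the comparison was read from known genes, because the header of the authors' deposited table does not state it. Positive values were taken as higher in EpiLSC, since Fgf5, Otx2 and Dnmt3b, markers of the epiblast after implantation, had positive values there and the naive markers Zfp42, Klf4 and Esrrb negative ones. The naive and formative lists are therefore not independent evidence of direction, although their movement in opposite directions does not rest on that choice. Levels given per state were computed from the mean and the fold change and carry no SD. Depth per sample was not given: the mean normalized counts of the table summed to 27888553, and the steps between low means gave size factors that differed by up to 1.74 times between the 4 libraries.

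The first question was which genes differ between the naive and the epiblast-like state. In the authors' deposited table, 1255 genes rose and 1019 fell in EpiLSC among 16361 genes with an adjusted p (DESeq2 Wald test, Benjamini-Hochberg adjusted p under 0.05). The largest rises among genes in the upper 50% of mean level were those of Enpp2, which makes lysophosphatidic acid, Car4, a carbonic anhydrase, Fat3, Tagln, Kif1a, Jakmip2, the growth factor gene Fgf5 and Fndc3c1. Enpp2 rose by a log2 fold change of 10.71 (SE 1.05) and Fndc3c1 by 8.31 (SE 0.75), per the authors' deposited table. The largest falls were those of Lrrc31, the cation channel gene Trpm1, Prdm14 and Tcl1 of the naive state, Myh13, Spic, Gm13128 and 1700061G19Rik. They ranged from Lrrc31 (-12.52, SE 1.52) to 1700061G19Rik (-9.40, SE 1.11) on the log2 scale of the authors' deposited table. In all of these but Kif1a, Fgf5 and Fndc3c1, the implied level of the lower state was under 3 normalized counts, so the sizes of their folds rest on few reads.

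A fold of 16 or more was reached by 656 of the genes that rose and 503 of those that fell, but in 628 of these 1159 the implied level of the lower state was under 3 normalized counts. Among all called genes this held for 644. Every called gene had changed by a log2 fold change of at least 1.68 in the authors' deposited table, so also requiring a fold of 2 left the counts at 1255 and 1019. Abundant genes fell more often than they rose: of 4949 tested genes with a mean of 1000 or more, 119 rose and 198 fell, while of 5648 with a mean below 100, 602 rose and 388 fell. The standard errors of the authors' deposited table were never below 0.605, and in simulated tables with these standard errors a 2-fold change was called for 1.2% of genes, a 4-fold change for 15.1% and a 16-fold change for 73.8%. The simulated tables held 200 changed genes each, against 2274 calls here. Their threshold was therefore stricter, and the shares called in the real table are likely higher. No change below a log2 fold change of 1.68 was called, so a gene that did not pass is not shown to be unchanged.

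**Figure D1:**
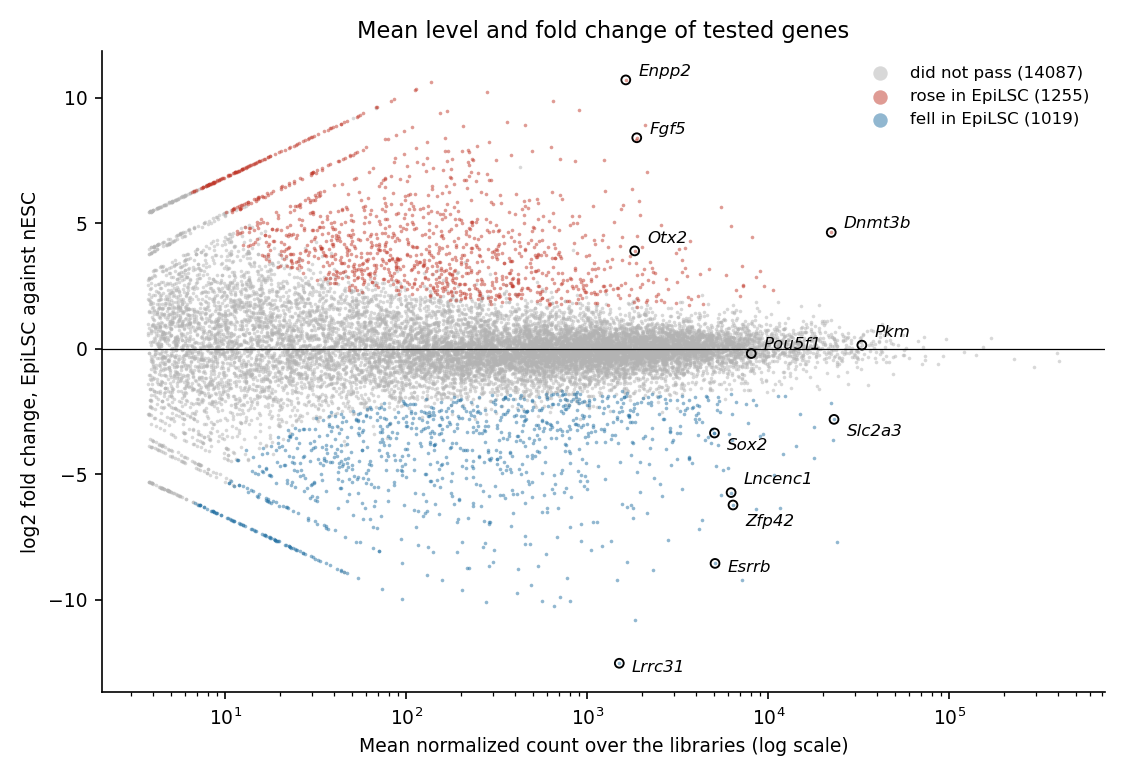
Each point is 1 of the 16361 tested genes of the authors' deposited table, with the mean normalized count over the libraries on a log axis and the log2 fold change of EpiLSC against nESC on the vertical axis. Red points rose (1255) and blue points fell (1019) at an adjusted p under 0.05. Circled genes are named: Fgf5 and Enpp2 lie at the top, Lrrc31, Esrrb, Zfp42 and Lncenc1 at the bottom, and Pou5f1 and Pkm near 0.

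The standard error depended on the mean level, with exceptions. Among the 4949 genes with a mean of 1000 or more, 17 had a standard error above 2 in the authors' deposited table, among them 11 replication-dependent histone genes and Hprt (SE 2.80), and none of the 17 was called. The noncoding gene Gm26917 (SE 3.00) and Lars2 (SE 2.69) had the highest means of the 17 in the authors' deposited table.

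**Figure D2:**
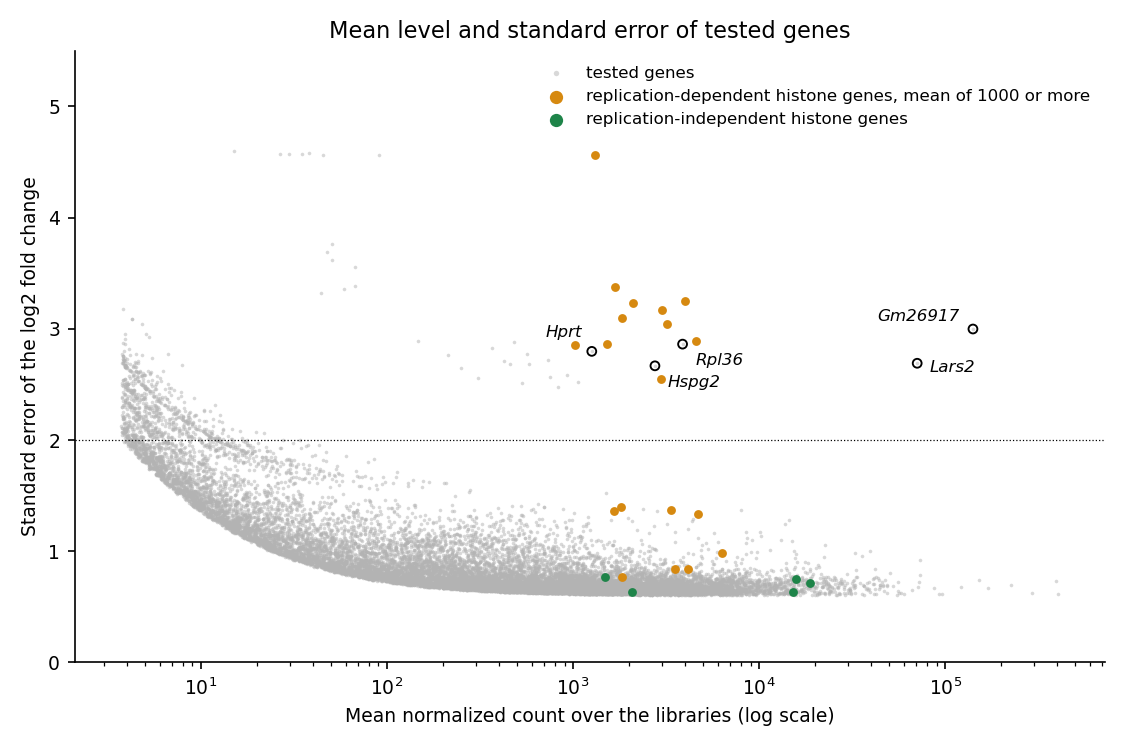
Each grey point is 1 of the 16361 tested genes, with the mean normalized count over the libraries on a log axis and the standard error of the log2 fold change from the authors' deposited table on the vertical axis. Orange points are the 19 replication-dependent histone genes with a mean of 1000 or more, 11 of them above the dotted line at 2, green points are 5 replication-independent histone genes, and circles mark 5 other named genes above that line.

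The second question concerned Lncenc1, the long noncoding RNA of the series title. Lncenc1 (ENSMUSG00000078952.8) fell 52.8-fold in EpiLSC, with a log2 fold change of -5.72 (SE 0.66, adjusted p 1.31e-15) in the authors' deposited table. Its mean normalized count was 6222 in the authors' deposited table, with implied levels of 12210 in nESC and 231 in EpiLSC. For comparison, the naive markers Zfp42 and Klf4 had values of -6.22 (SE 0.62) and -6.29 (SE 0.68) in the authors' deposited table. Among long noncoding RNAs with a mean in the upper 50% of tested genes, the largest falls were those of 1700097N02Rik (-5.80, SE 0.71), Lncenc1, C78283 (-5.37, SE 0.71), Platr16 (-5.37, SE 0.76) and 1700030C10Rik (-4.91, SE 0.71), per the authors' deposited table. Of this group 16 fell and 2 rose, Ftx by 3.24 (SE 0.68) and Snhg14 by 2.85 (SE 0.73) in the authors' deposited table; tested against a 2-fold change, Snhg14 no longer passed (adjusted p 0.131, range 0.00114 to 0.131 over its alternatives).

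The third question was which gene groups moved with the state, over 27 gene lists fixed before the data were examined. All 18 members of the naive pluripotency list fell, over all genes tested and adjusted over the list alone, and their median log2 fold change was -6.84. The smallest p in the list belonged to Jam2 (-9.22, SE 0.74), which encodes an adhesion molecule, and the nuclear receptor gene Nr5a2 (-8.81, SE 0.71), per the authors' deposited table. Esrrb (-8.54, SE 0.69) and Tbx3 (-7.60, SE 0.76) fell in the authors' deposited table, as did Nanog (-2.25, SE 0.75, adjusted p 0.0238). The call of Nanog ended when it was tested against a 2-fold change (adjusted p 0.666, range 0.0238 to 0.666 over its alternatives). The list as a whole lay lower than other genes (cameraPR, adjusted p 1.21e-63).

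In the formative and primed epiblast list, 18 of 20 members rose, over all genes tested and adjusted over the list alone (median log2 fold change 3.97, cameraPR adjusted p 3.27e-27). The authors' deposited table gave rises of 8.40 (SE 0.76) for Fgf5, 8.04 (SE 0.88) for the POU factor gene Pou3f1 and 3.90 (SE 0.66) for Otx2. Tead2 (1.23, SE 0.79) and Cdh2 (0.72, SE 0.70) did not pass in the authors' deposited table. The core pluripotency list, whose members are shared by both states, had 1 fall among 12 genes over all genes tested and adjusted over the list alone. Sox2 fell by 3.35 (SE 0.64), while Pou5f1 (-0.19, SE 0.76), Lin28a (1.86, SE 0.71), Foxd3 (1.39, SE 0.79) and Dppa2 (-1.36, SE 0.89) did not pass in the authors' deposited table. Its test was not past the threshold (cameraPR, adjusted p 0.763), with a median of 0.10 and a direction below that of other genes.

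The enzymes that set and remove DNA methylation split: 3 of 12 rose and 2 fell, over all genes tested and adjusted over the list alone. The methyltransferase genes Dnmt3b and Dnmt3a rose by 4.63 (SE 0.63) and 2.92 (SE 0.63), and the oxidase gene Tet3 by 2.49 (SE 0.74), in the authors' deposited table. Tet2 (-4.74, SE 0.69) and Dnmt3l (-2.93, SE 0.71), a cofactor of the methyltransferases, fell in the authors' deposited table. Taken as a list they did not pass (cameraPR, adjusted p 0.757).

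The glycolysis list, named for the process in the series title, did not pass as a whole, which does not show that it was unchanged: of 29 genes 1 rose and 4 fell, over all genes tested and adjusted over the list alone (cameraPR, adjusted p 0.469). Its median log2 fold change was 0.15, its mean -0.22, and its test pointed down. The phosphofructokinase gene Pfkp (-3.40, SE 0.70), the glucose transporter gene Slc2a3 (-2.81, SE 0.67), Hk1 (-2.61, SE 0.95) and Ldhb (-2.52, SE 0.66) fell in the authors' deposited table. The lactate transporter gene Slc16a3 rose by 2.71 (SE 0.90) in the authors' deposited table. Slc2a1 (0.44, SE 0.88), Hk2 (-1.00, SE 0.67), Pgk1 (0.33, SE 0.71), Eno1 (0.14, SE 0.71), Pkm (0.15, SE 0.98) and Ldha (1.09, SE 0.64) did not pass in the authors' deposited table. Of the 24 members that did not pass, 9 had a 95% interval that lay within a 4-fold change either way. Tested against a 2-fold change, of the 5 calls only that of Pfkp stood (adjusted p 0.0124, range 2.42e-05 to 0.0124 over its alternatives). Slc2a3 (0.0878, range 0.000414 to 0.0878), Ldhb (0.213, range 0.00171 to 0.213), Slc16a3 (0.464, range 0.0214 to 0.464) and Hk1 (0.633, range 0.045 to 0.633) lost theirs. Hk1 also lost its call with no filter (adjusted p 0.0559) and among genes with a mean of 100 or more (0.0518).

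**Figure D3:**
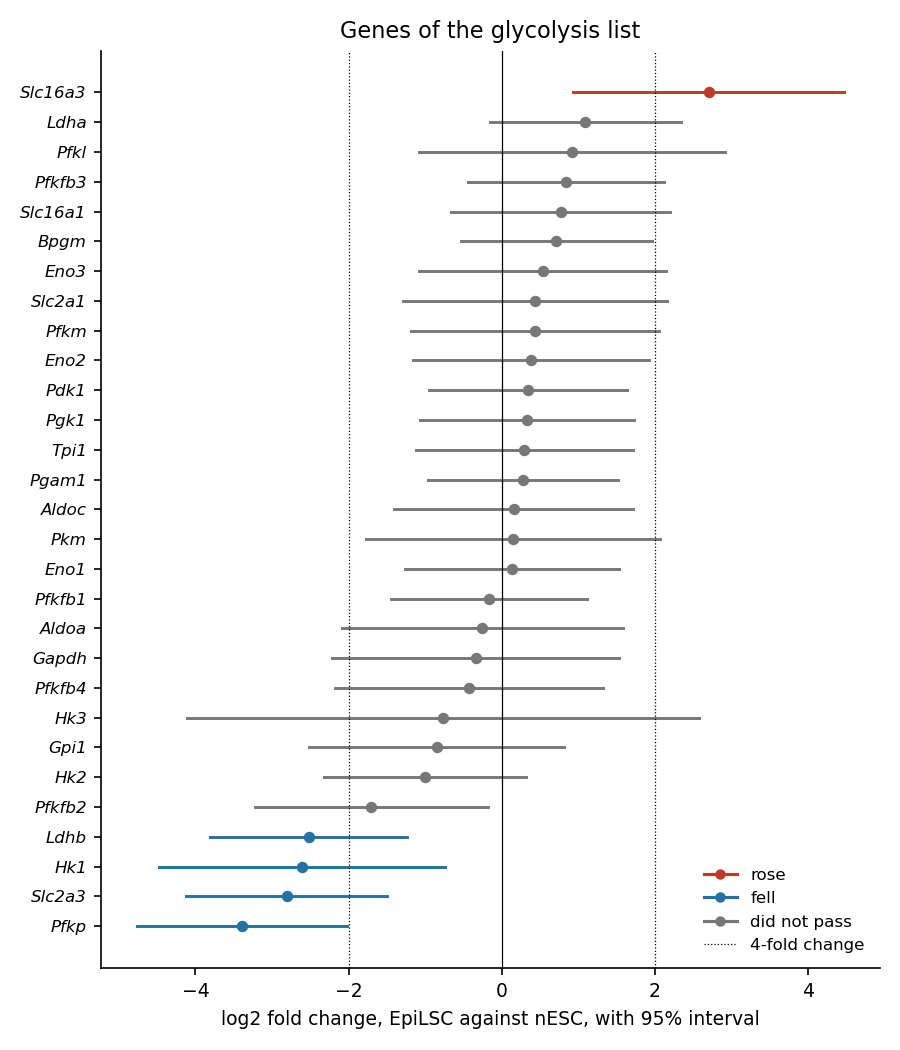
Log2 fold change of EpiLSC against nESC for the 29 genes of the glycolysis list, with 95% intervals computed from the standard errors of the authors' deposited table. Red genes rose, blue genes fell, grey genes did not pass, and dotted lines mark a 4-fold change. Pfkp, Slc2a3, Hk1 and Ldhb lie to the left and Slc16a3 to the right of the other 24 genes.

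Oxidative phosphorylation, the TCA cycle and cholesterol synthesis had no called gene. Among 75 nuclear genes of oxidative phosphorylation 0 rose and 0 fell over all genes tested and adjusted over the list alone, and 0 had an unadjusted p under 0.05 (DESeq2 Wald test; list cameraPR adjusted p 0.231). The extremes by p were Cox6a1 (-1.08, SE 0.83), Cox6b1 (-0.78, SE 0.63), Ndufc2 (0.41, SE 0.63) and Ndufab1 (0.36, SE 0.69) in the authors' deposited table. The 13 mitochondrially encoded genes also had 0 calls by either count and 0 at an unadjusted p under 0.05, with mt-Nd3 at 0.34 (SE 0.82) and mt-Nd5 at -0.27 (SE 0.84) in the authors' deposited table (DESeq2 Wald test; list cameraPR adjusted p 0.951). For the 21 genes of pyruvate dehydrogenase and the TCA cycle the calls were 0 by either count and 1 gene, Idh2 (-2.03, SE 0.87 in the authors' deposited table), had an unadjusted p under 0.05 (DESeq2 Wald test; list cameraPR adjusted p 0.38). The cholesterol synthesis list had 0 calls among 20 genes by either count and 1 at an unadjusted p under 0.05, Ebp, at -1.27 (SE 0.64) in the authors' deposited table (DESeq2 Wald test; list cameraPR adjusted p 0.349). In the serine, threonine and one-carbon list 1 of 15 genes fell by either count, Tdh (-4.81, SE 0.67), the threonine dehydrogenase gene, in the authors' deposited table (list cameraPR adjusted p 0.376).

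FGF and ERK targets rose and LIF and STAT3 targets fell as lists. The 2 states were kept in different media, 2i/LIF for nESC and bFGF with activin A for EpiLSC. Effects of the medium on these and other genes therefore cannot be told apart from the change of state. Of 19 FGF and ERK targets 9 rose over all genes tested and 11 adjusted over the list alone, and 0 fell (median log2 fold change 2.18, cameraPR adjusted p 1.13e-06). The phosphatase gene Dusp4 rose by 5.29 (SE 0.68) and the early response gene Egr1 by 7.52 (SE 1.08), whereas Etv5 (-0.99, SE 0.66) and Dusp14 (-0.63, SE 0.85) did not pass in the authors' deposited table. Of 14 LIF and STAT3 targets 8 fell and 0 rose by either count (median -2.50, cameraPR adjusted p 3.76e-08). Tfcp2l1 (-7.71, SE 0.64) and Klf4 (-6.29, SE 0.68) fell, while Myc (1.92, SE 1.03) and Junb (3.47, SE 2.77) did not pass in the authors' deposited table. This list shares 4 genes with the naive list, Gbx2, Klf4, Klf5 and Tfcp2l1, which are 4 of its 8 falls. The other falls were those of Stat3, Bcl3, Lifr and Il6st, while Socs3, Pim1, Pim3 and Osmr also did not pass. When tested against a 2-fold change, Stat3, Bcl3, Lifr and Il6st lost their calls, as did the shared genes Gbx2 and Klf5. No list test was made without the shared genes, so the fall of this list is not separate from that of the naive list.

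The activin and Nodal targets had 3 rises and 1 fall among 12 genes by either count (cameraPR, adjusted p 0.112). Fgf8 rose by 4.52 (SE 1.29) and Lefty2 fell by 3.06 (SE 0.61), in the authors' deposited table. Of 15 Wnt and beta-catenin targets 2 rose and 5 fell by either count (cameraPR, adjusted p 0.144, median 0.02, mean -0.87, test direction down). Notum (-7.43, SE 0.97) and Sp5 (-4.01, SE 0.72) fell, and Lef1 rose by 3.24 (SE 0.71) and Lgr5 by 8.02 (SE 1.90), in the authors' deposited table.

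Markers of other cell types were partly called in both directions. The mesoderm and endoderm list had 5 rises and 2 falls among 12 genes by either count (cameraPR, adjusted p 0.103), with Wnt3 at 5.37 (SE 0.81), Foxa2 at 6.60 (SE 1.59), Kdr at -4.06 (SE 0.99) and Cdx2 at -5.55 (SE 1.42) in the authors' deposited table. Among 11 neuroectoderm genes 4 rose, 5 adjusted over the list alone, and 1 fell (cameraPR, adjusted p 0.231), with Nes at 3.19 (SE 0.68) and Ncam1 at -3.01 (SE 0.72) in the authors' deposited table. The primitive endoderm list had 5 rises and 2 falls among 14 genes, 5 and 3 adjusted over the list alone (cameraPR, adjusted p 0.757), with Col4a1 at 4.28 (SE 1.01) and the laminin gene Lama1 at -5.58 (SE 0.69) in the authors' deposited table. In the trophectoderm list 2 of 12 genes rose and 5 fell by either count (cameraPR, adjusted p 0.103), with Krt18 at 4.87 (SE 1.06), Tfap2c at -5.82 (SE 0.77) and Tead4 at -4.94 (SE 0.72) in the authors' deposited table. The fibroblast and feeder cell list had 6 rises and 0 falls among 11 genes, 7 and 0 adjusted over the list alone (median log2 fold change 4.04, cameraPR adjusted p 0.000493), with Mmp2 at 4.05 (SE 0.82) and Thy1 at 4.60 (SE 0.97) in the authors' deposited table. Pdgfrb, at -1.24 (SE 1.00), did not pass in the authors' deposited table. For the 7 tested genes of the 2-cell-like state, several of them near-identical copies that can share reads, the calls were 0 by either count and 0 at an unadjusted p under 0.05 (DESeq2 Wald test; list cameraPR adjusted p 0.294), with Tdpoz3 at -4.34 (SE 2.36) in the authors' deposited table.

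Adhesion genes changed in both directions: 6 of 14 rose and 3 fell by either count, and as a list they did not pass (cameraPR, adjusted p 0.103), although they did among genes with a mean of 100 or more (adjusted p 0.0336, range 0.0336 to 0.222 over the alternatives). The tight junction genes Cldn6 and Cldn7 rose by 4.91 (SE 0.80) and 5.60 (SE 0.93), while the repressor gene Zeb1 (-4.51, SE 0.67) and the intermediate filament gene Vim (-2.79, SE 0.66) fell in the authors' deposited table. The mesenchymal regulator genes Zeb2 and Twist1 rose, by 5.04 (SE 0.94) and 4.26 (SE 0.79) in the authors' deposited table. Of 20 germline genes 5 rose and 8 fell, 5 and 9 adjusted over the list alone (cameraPR, adjusted p 0.145). Among them Sycp2 rose by 4.50 (SE 0.75) and Tdrd1 by 5.16 (SE 0.86), and Prdm1 (-4.37, SE 0.68) and Sohlh2 (-4.80, SE 0.79) fell, in the authors' deposited table. Of 28 imprinted genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.99, cameraPR adjusted p 0.0179). Magel2 rose by 7.04 (SE 1.31) and Grb10 by 2.55 (SE 0.63), and Plagl1 fell by 5.26 (SE 1.21), in the authors' deposited table. The imprinted call ended with a preset correlation of 0.05 (adjusted p 0.144) and among genes with a mean of 100 or more (adjusted p 0.0745, range 0.0102 to 0.144 over the alternatives).

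Of 16 p53 targets 2 rose by either count, Pmaip1 by 5.07 (SE 0.85) and Perp by 3.11 (SE 0.75) in the authors' deposited table (list cameraPR adjusted p 0.231). The hypoxia list had 1 rise among 16 genes, Egln3 by 1.99 (SE 0.72) in the authors' deposited table, and 0 adjusted over the list alone (cameraPR, adjusted p 0.231, 5 genes at an unadjusted p under 0.05 in the DESeq2 Wald test). Egln3 lost its call with no filter and when tested against a 2-fold change (adjusted p 0.0384 to 0.993 over its alternatives). The cell cycle list had 1 rise and 1 fall among 28 genes by either count, Ccnd2 (4.17, SE 0.74) and Cdkn2a (-4.13, SE 1.08) in the authors' deposited table (list cameraPR adjusted p 0.75).

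Among 54 named long noncoding RNAs 7 rose and 18 fell, 7 and 19 adjusted over the list alone (median log2 fold change -0.73, cameraPR adjusted p 0.000493). Lncenc1 and Platr16 had the smallest p among the falls, and Miat, which rose by 6.71 (SE 0.81), and Ftx those among the rises, per the authors' deposited table. The Platr RNAs carried this fall: of 25 in the list 14 fell and 1 rose (median -2.90), while of the other 29 members 6 rose and 4 fell (median 0.19). Without the Platr RNAs the list did not pass (adjusted p 0.967), and the call also ended with a preset correlation of 0.05 (adjusted p 0.0549, range 0.000265 to 0.967 over the alternatives). Xist rose by 3.69 (SE 0.87) and its antisense partner Tsix fell by 2.04 (SE 0.70) in the authors' deposited table, but whether the counting used the strand is not given in the sources used here, so the values of overlapping pairs are uncertain. Of the list of structural and leftover ribosomal RNAs 1 member of 15 was in the table, Lars2, at -0.61 (SE 2.69) in the authors' deposited table, and no list test was made.

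In all, 7 of the 27 lists tested passed. They were tested with a preset correlation of 0.01 between genes, and a correlation estimated from the samples could not be used without values per sample. Among the called genes named in these lists, Dnmt3l, Tet3, Fgf8, Ncam1, Vim, Grb10, Perp, Cdkn2a and Tsix also lost their calls when tested against a 2-fold change, as did Nanog, Snhg14, Egln3 and 4 genes of glycolysis above. The same held for Stat3, Bcl3, Lifr, Il6st, Gbx2 and Klf5. For Lgr5, Fgf8, Foxa2, Cdx2 and Magel2 the implied level of the lower state was under 3 normalized counts, so their folds rest on few reads.

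**Figure D4:**
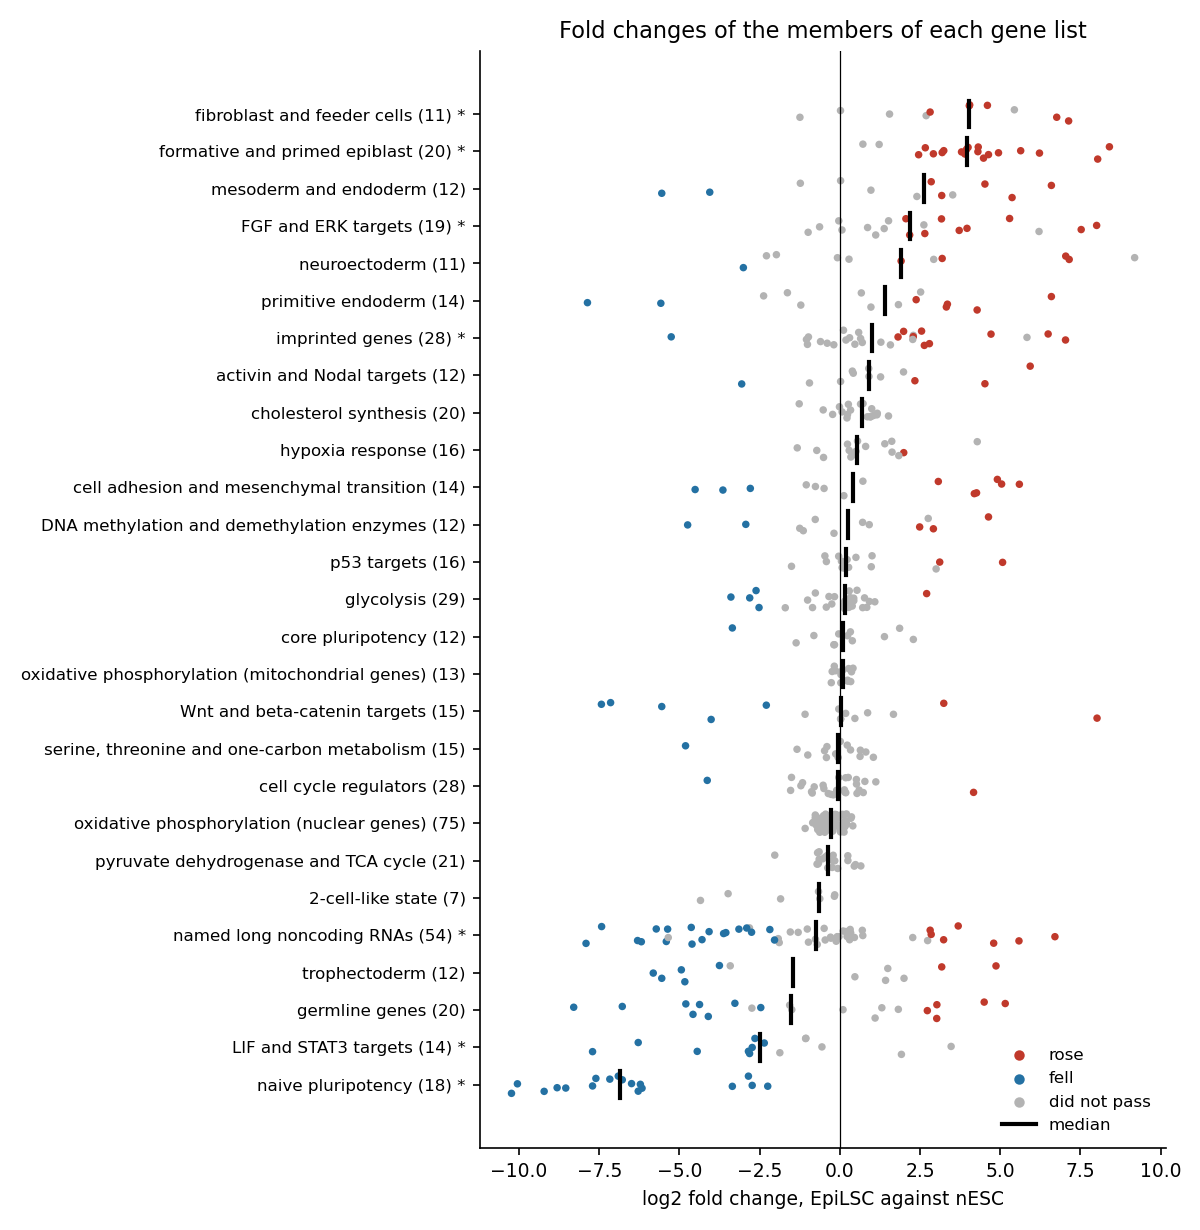
Log2 fold changes of EpiLSC against nESC in the authors' deposited table for the members of the 27 tested gene lists, with the number of tested members in brackets and a star for a list with an adjusted p under 0.05. Red points rose, blue points fell, grey points did not pass and black bars are list medians, with vertical scatter added for legibility. The naive list lies lowest with a median of -6.84, and the formative list has a median of 3.97.

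The comparison of R1 with E14 could not be made from a table without values per sample.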

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

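No paired analysis was possible because the table holds no values per sample, so the cell line could not enter a model as a block. For the same reason leaving out samples, other normalizations, other pseudocounts, the edgeR and DESeq2 fits of counts, fry, camera with an estimated correlation and the comparison of R1 with E14 were not run. Of the alternatives fixed before the data were examined, no filter beyond a nonzero total gave 1185 rises and 965 falls, all among the main calls, and requiring a fold of 2 changed no count. The others were chosen after the data were seen. Tested against a 2-fold change, 628 genes rose and 502 fell, fewer because that test is stricter. Among genes with a mean of 100 or more, 636 rose and 615 fell, as only 10713 genes were tested. With recentred fold changes the counts were 1276 and 995. Lncenc1 passed under every alternative run for it, and the naive and formative lists passed and the glycolysis list did not under every one run for them. Over all results and alternatives, 606 of 640 values kept their side of the threshold or their size of count, 33 were weaker, 1 was stronger and 0 reversed. The weaker ones include the lower counts under the 2-fold test and under the mean of 100. The 109 values from also requiring a fold of 2 could not change, because every called gene already met it. Recentring took off a median of only -0.03 from each log2 fold change, so its 137 values, all the same, could change little. Under the test against a 2-fold change 86 values were the same and 23 weaker. Single genes in these counts were those of the naming rule that were called or fixed by name, the called glycolysis genes and others. The others were Tet3, Zeb2, Twist1, Xist, Tsix, Enc1, Pcdh11x, Pcdh19, Hoxc4, Hoxc13, Fbn1, Dcn, Acta2 and Loxl1. The called genes Stat3, Bcl3, Lifr, Il6st, Gbx2 and Klf5 were not followed in these counts, and they too did not pass the 2-fold test. In all, 100 called genes were followed. Of these 21 lost the call, all when tested against a 2-fold change. With the range of adjusted p over their alternatives they were Nanog (0.0238 to 0.666), Snhg14 (0.00114 to 0.131), Slc2a3 (0.000414 to 0.0878), Ldhb (0.00171 to 0.213), Slc16a3 (0.0214 to 0.464), Hk1 (0.045 to 0.633) and Egln3 (0.0384 to 0.993). Further ones were Perp (0.000477 to 0.0668), Dnmt3l (0.000565 to 0.0858), Fgf8 (0.00487 to 0.0829), Ncam1 (0.000458 to 0.072), Eomes (0.00403 to 0.164), Grb10 (0.000661 to 0.154) and Vim (0.000351 to 0.0843). The rest were Cdkn2a (0.00186 to 0.0548), Tet3 (0.00685 to 0.372), Tsix (0.029 to 0.863), Enc1 (0.0337 to 1), Pcdh19 (0.0106 to 0.414), Fbn1 (0.00122 to 0.139) and Loxl1 (0.0385 to 0.327). Hk1, Egln3 and Loxl1 also lost the call with no filter, and Hk1 among genes with a mean of 100 or more. Of all 84 called genes named by the rule, 71 passed the 2-fold test and 83 passed with no filter. Calls were also lost by the lists of imprinted genes (0.0102 to 0.144) and named long noncoding RNAs (0.000265 to 0.967, the highest without the Platr RNAs), while the adhesion list gained one (0.0336 to 0.222). Depth limits genes with low means most: the median standard error was 1.3 at a mean below 100.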

Other observations

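The tests of histone genes, of Hprt, of the collagens and of gene families, the count of 9 of 15 genes by GC, the lean of the metabolic lists and the value of Enc1 were chosen only after results were seen. The neighbours without overlapping pairs were run before all pairs, although the rule written beforehand named all pairs.

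Of 263 gene families that share a symbol stem and have 8 or more tested members, 12 passed the list test. Of 10 protocadherin genes of the Pcdh family 9 rose and 1 fell (median log2 fold change 5.73, cameraPR adjusted p 1.11e-06), led by Pcdh11x at 10.32 (SE 1.67), with Pcdh19 at -2.48 (SE 0.76) in the authors' deposited table; the call of Pcdh19 ended when tested against a 2-fold change (adjusted p 0.0106 to 0.414 over its alternatives). The 12 tested Pcdhga genes had 0 calls and a median of -1.27, and did not pass (adjusted p 0.158, test direction down). Of 9 Hoxc genes 6 fell and 0 rose (median -5.42, adjusted p 0.000121), with Hoxc13 at -4.03 (SE 0.95) and Hoxc4 at -5.77 (SE 1.26) in the authors' deposited table. In 8 of the 10 called Pcdh genes and 5 of the 6 called Hoxc genes the implied level of the lower state was under 3 normalized counts, so these folds and medians rest on few reads. The synaptotagmin genes had 6 rises among 12 (adjusted p 8.65e-05) and the Serpinb genes 5 falls among 9 (adjusted p 1.11e-06). The smallest p was that of the Platr RNAs (cameraPR, adjusted p 9.85e-08), which are part of the named long noncoding RNA list. Families were formed by symbol stem alone. A shared name need not mean a shared sequence, nor that members were named without regard to their expression.

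Of the 4 metabolic lists without a called gene 3 leaned narrowly to 1 side. Of 75 nuclear genes of oxidative phosphorylation 56 had a fold change below 0 (median -0.27, percentile 0.4 among 10000 mean-matched random lists), and 16 of 20 cholesterol synthesis genes had one above 0 (median 0.68, above 100% of such lists). The pyruvate dehydrogenase and TCA cycle list had 16 of 21 genes below 0 (median -0.38, percentile 0.9), while the 13 mitochondrially encoded genes did not lean (median 0.08, percentile 54.3). None of the 4 passed cameraPR, and random lists ignore correlation between genes. Nor were they matched on GC, with which the fold change had a Spearman rho of -0.25 and a Pearson r of -0.13 over 4944 abundant genes. Extreme percentiles were not particular to metabolic lists. Germline and trophectoderm genes lay at 0.0, and activin and Nodal targets and mesoderm and endoderm genes at 99.9, without passing cameraPR. Glycolysis (80.8) and cell cycle (28.6) genes were not extreme. Among 4949 abundant genes 72.9% had a fold change within 1 standard error of 0, against 68.3% for a normal distribution, so the deposited errors were wide beside the spread of fold changes. Enc1, the nearest coding gene to Lncenc1 in GENCODE M21, lies 181936 bp from it. Enc1 rose by 1.76 (SE 0.63, adjusted p 0.0386) in the authors' deposited table, but did not pass when tested against a 2-fold change (adjusted p 0.0337 to 1 over its alternatives).

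Among genes with a mean of 1000 or more, 17, among them 11 replication-dependent histone genes, Gm26917, Lars2 and Hprt, had a standard error above 2 and up to 4.56 in the authors' deposited table, against at most 1.52 for the others. Their median transcript GC of 63.3% lay above 100% of 10000 mean-matched sets (central 95% from 43.5% to 50.1%), so GC-dependent differences between libraries may contribute. With 11 histone genes among the 17, GC cannot be told apart from gene class in that median. The 6 non-histone genes had a median GC of 60.9%, and no matched sets were drawn for them alone. Of the 15 abundant genes with a GC at or above 63.3%, 9 were among the 17, a number fixed by taking their median as the cutoff. On the other hand, the rest of those 15 genes had a median standard error of 0.75. Over 4927 other abundant genes error and GC had a Spearman rho of -0.08 and a Pearson r of 0.19 (median error 0.70 in the 20% with the lowest and 0.71 in the 20% with the highest GC). The 19 abundant replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median standard error of 2.86, but 11 of them had been picked for an error above 2, which fixes that median, so uneven recovery of such RNA was not tested, nor were reads shared between near-identical histone copies. Hprt, with a GC of 40.1%, had a standard error of 2.80 in the authors' deposited table; its percentile of 99.8 among the 1000 genes of nearest mean follows from how it was picked, so a difference between the cell lines at Hprt, in which E14TG2a is known to be deficient, stays untested without values per sample.

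Of 184 called long noncoding RNAs 70.1% fell, against 42.4% of 2080 called coding genes. Level of expression does not account for this, since called coding genes drawn at the same means fell in 34.9% of cases (central 95% from 28.3% to 41.3%). Reads of overlapping coding genes do not either, since of 94 called noncoding RNAs that overlap no coding gene 77.7% fell (Wilson 95% interval 68.2% to 84.9%). Of 70 called nearest coding genes 39 fell, 55.7% (Wilson 95% interval 44.1% to 66.8%), and in 63 of these pairs both moved the same way. The 70 pairs include overlapping ones, whose values are uncertain, and pairs moving the same way were not counted without those. Fold changes did correlate over 577 pairs without overlap, which were not limited to called genes (Spearman rho 0.37, Pearson r 0.37). Their median distance was 4.4 kb. That correlation does not give the share of falls. Among called nearest coding genes without overlapping pairs, the share of falls was 62.1% of 29 (44.0% to 77.3%). A change shared with the neighbouring coding gene may therefore be part of the pattern, as a hypothesis, though both lower bounds lie close to 42.4% and the share of falls among the noncoding RNAs lies above the upper bound of 66.8%.

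The rise of the fibroblast list may come from fibroblasts or feeder cells in the EpiLSC cultures, although the labels name gelatin-coated plates and no feeder layer. Fibroblasts bring abundant fibrillar collagen RNA, and Col1a1, Col1a2 and Col3a1 together could reach at most 51.2 normalized counts in EpiLSC. This lies below the implied EpiLSC levels of Fbn1 (548), Mmp2 (205) and Thy1 (141), which argues against such cells as the source of those rises. For Dcn (52.6), Acta2 (68.2) and Loxl1 (42.5) the implied collagen sum of 43.7 reached only the level of Loxl1, so fibroblasts stay open as a source for these low genes. A change of the epiblast-like cells themselves was not tested.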
